A study of Mus musculus with 4 samples.

How the data were processed

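Gene expression was measured by RNA sequencing in 2 libraries of intraepithelial mast cells (IEMC) and 2 libraries of lamina propria mast cells (LPMC) that were sorted from the intestine of infected wild-type mice at day 14. Per the labels, RNA was extracted and libraries were made with kits of a sequencing company, and the submitters' processing notes name HISAT, Bowtie2 and the mouse build GRCm39, without versions or roles. The annotation, the counting program, the use of strand and the gates of the sort are not given in the sources used here. Where reads of a gene and an overlapping antisense gene were counted without strand they cannot be told apart.

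The deposited table gives, per the file headers, a read count, an FPKM value and a TPM value for each gene and library, and the authors' mean of each over the libraries of a group. The deposited read counts are estimated counts, since 20.8% to 22.5% of the values per library were not whole numbers. FPKM values, per the file headers, are the authors' values per kilobase of transcript and per library size, and TPM values, per the file headers, are the authors' values scaled to a common total per library, which keep no depth. The authors' mean columns equalled the means of the library columns to within 1.16e-10 and were used only for that check. The table holds 15722 genes with gene IDs and symbols, of which 15601 (99.2%) matched a reference table of mouse genes on the GRCm38.p6 assembly, and 15588 had the same symbol there. That table was used only for names and for which genes neighbour each other, and no coordinates are given because its build is not that of the files.

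Groups and replicate numbers were taken from the titles of the libraries. The estimated counts were rounded to whole numbers. Genes with low counts were removed with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 12390 genes, and libraries were scaled by the trimmed mean of M values (TMM factors 1.04, 1.01, 0.989 and 0.96 for IEMC replicates 2 and 4 and LPMC replicates 2 and 4). IEMC was compared with LPMC by edgeR's quasi-likelihood test, with group as the only term and Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p under 0.05. Adjusted p-values given for genes are from this test unless another is named. CPM is the read count scaled to library size. With total counts of 23345915 to 24932446 per library and the TMM factors, 1 count was worth 0.0396 to 0.0441 CPM. The 10 most abundant genes took 15.7% and 15.9% of the counts of the IEMC libraries and 10.1% and 9.5% of those of the LPMC libraries. Where a group had 0 counts the fold is given as a lower bound against 3 counts over the group. With 1 to 3 counts the ratio is given with its 95% counting interval.

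Before the data were examined, 28 gene lists were fixed from general knowledge of mast cells, the gut and worm infection, among them markers of other cell types and genes that respond to tissue handling. Ccl5, Cx3cr1, Ccr3, Il3ra and Pecam1 stand in more than 1 list. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the 27 tested lists, and members were also adjusted over the list alone. The list of mitochondrially encoded genes was not analysed here, and neither were list members without a tested row, such as Mcpt10 and the constant genes of T cell receptors and immunoglobulins. The rule for named genes was fixed at the same time. It takes the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among called genes with a mean of at least 10 CPM in the higher group and groups that do not overlap, without predicted genes, pseudogenes and receptor segments. It adds up to 4 tested members of each list by smallest p with both directions represented where called members go both ways, 17 genes named whatever their values (Mcpt1, Mcpt2, Mcpt4, Cma1, Cpa3, Tpsb2, Tpsab1, Kit, Fcer1a, Itgae, Il4, Il5, Il13, P2rx7, Il1rl1, Epcam and Ptprc), and the 3 most abundant genes of each group by TPM. Genes outside the rule are marked as chosen after their values were seen. Some genes that the rule takes are not reported here.

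The alternatives fixed before the data were examined were scaling by RLE size factors, by the upper quartile or by library size only, no filter on low counts except a total above 0, a filter of at least 10 counts in every sample of a group, the replicate number as a block, a test against a fold of 1.5, robust moderation, DESeq2 1.42.0 without independent filtering, limma on log2(FPKM + 1) and log2(TPM + 1) and with 0.1 in place of 1, leaving out each library in turn, leaving out genes of other cell types, and for lists an estimated correlation and the rotation test fry. Those meant for a table without counts did not apply. Limma used genes with a value of at least 1 in at least 2 samples. Counts of called genes whose higher group had its libraries within 1.5-fold of each other were added after the data were seen.

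The tests were tested on simulated counts for the comparison of IEMC with LPMC, with 200 genes changed by known folds. Of 12072 simulated genes in that step, edgeR's quasi-likelihood test recovered 47 of 100 genes changed by a fold of 2 and 72 of 100 changed by a fold of 4, with 5 calls among unchanged genes, and DESeq2 recovered 58 and 82 with 30 such calls. For a simulated list of raised genes, camera gave an adjusted p of 6.61e-28 with the preset correlation and 0.243 with an estimated correlation. Fry gave an adjusted p of 0.115, and none of these called any of 26 unchanged lists. The simulated genes were drawn independently and put into lists at random, so these lists held no correlation between genes. They therefore cannot show how often the preset correlation calls unchanged lists of correlated genes. Figures were drawn with matplotlib 3.10.9.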

Results

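Mast cells were sorted from the intestine of wild-type mice 14 days after infection with larvae of H. polygyrus, a nematode that lives in the small intestine of mice. Intraepithelial mast cells (IEMC) came from the epithelium and lamina propria mast cells (LPMC) from the lamina propria, the connective tissue beneath it. RNA was sequenced from 2 IEMC libraries and 2 LPMC libraries, numbered 2 and 4 in each group. The total estimated count was 24049648 in IEMC replicate 2 and 24932446 in IEMC replicate 4. It was 23345915 in LPMC replicate 2 and 23662427 in LPMC replicate 4. With the TMM scaling factors, 1 count was worth 0.0396 to 0.0441 normalised CPM. Levels are in CPM, the read count scaled to library size and TMM factor, given as mean ± SD with n = 2 libraries per group. Log2 fold changes are IEMC minus LPMC. Across genes, log2 CPM correlated at r = 0.968 between the IEMC libraries, at r = 0.95 between the LPMC libraries and at r = 0.83 to 0.848 between libraries of different groups. Both pairs of replicates differed by more than sampling noise (chi-square per degree of freedom 19.8 and 42.5). Nothing in the labels says that the libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical.

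The comparison of IEMC with LPMC asked how mast cells of the epithelium differ from those of the lamina propria in the same infection. IEMC carried far more RNA for the integrin Itgae, the mucosal protease Mcpt9 and the chymase Cma2. LPMC carried far more for the tryptase Tpsb2, the chymase Cma1, the histamine-forming enzyme Hdc and the granzyme Gzmb. Itgae, the alpha chain of the integrin that binds E-cadherin, was at 2867 ± 60.5 CPM in IEMC and 7.31 ± 0.809 CPM in LPMC (log2 fold change 8.61, SE 0.15, adjusted p = 1.09e-05). Hdc was at 10.5 ± 0.342 CPM in IEMC and 5629.8 ± 741 CPM in LPMC (log2 fold change -9.07, SE 0.17, adjusted p = 1.09e-05). Cma2, a chymase chosen after its values were seen, was 154-fold higher in IEMC at 4150.3 ± 623 against 26.9 ± 5.05 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3246 of 12390 tested genes differed at the adjusted p threshold of 0.05. Of these, 1538 were higher and 1708 lower in IEMC, a balance that turned to 1842 higher and 1457 lower under upper quartile scaling and to 1843 higher and 1577 lower without LPMC replicate 4. A fold change of at least 2 was seen for 1037 of the higher and 1053 of the lower genes. The number of calls fell to 1598 without IEMC replicate 2 and to 1556 without IEMC replicate 4, and 1684 genes passed a test against a fold of 1.5. Of the 27 gene lists tested, 3 were called up and 13 down in IEMC with the preset correlation of camera. With an estimated correlation 0 passed, and the smallest adjusted p was 0.399. A simulated list of raised genes did not pass with an estimated correlation either (camera adjusted p = 0.243). Not passing with it, here and below, therefore does not show that a list was unchanged.

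**Figure D1:**
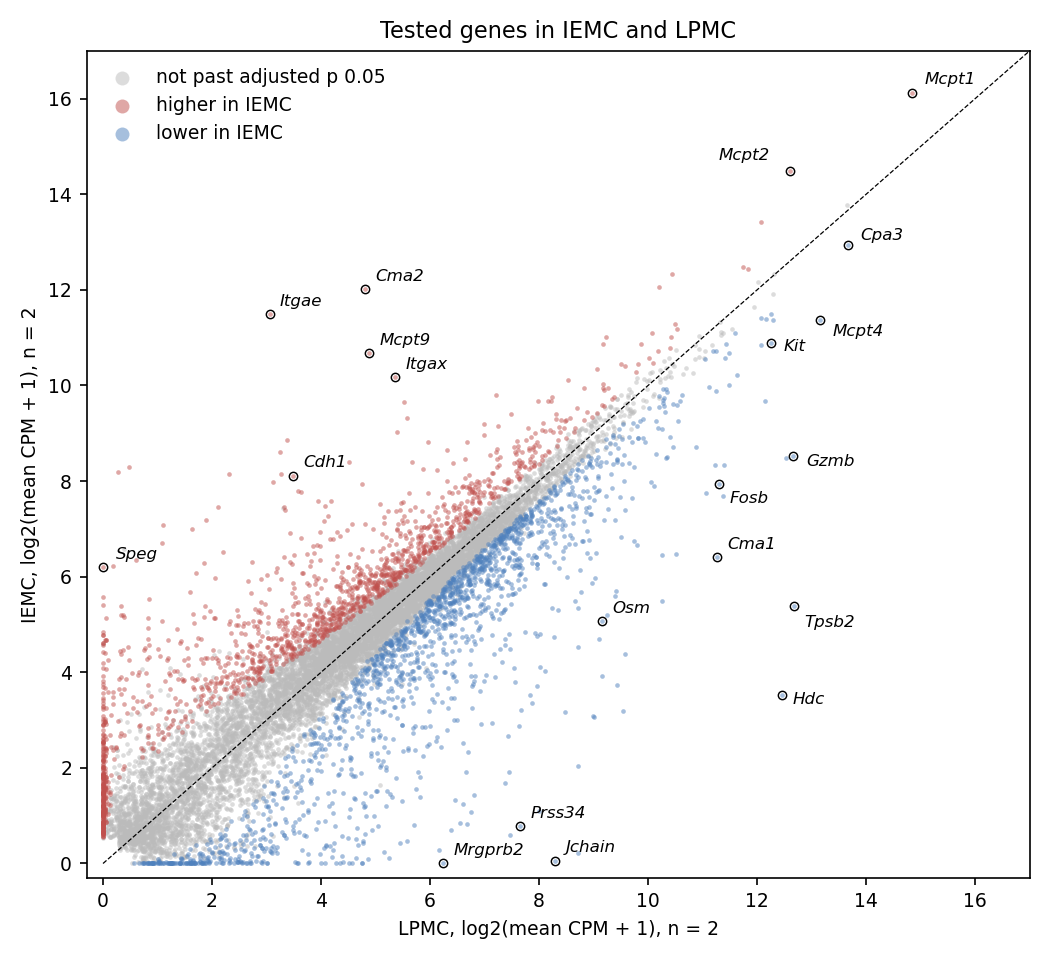
Mean level of each tested gene in LPMC (x axis) and IEMC (y axis), as log2(mean CPM + 1) over 2 libraries per group, with the dashed line at equal levels. The 1538 genes called higher in IEMC lie above the line and the 1708 called lower lie below it, and among the marked genes Itgae and Cma2 lie farthest above and Hdc and Jchain farthest below.

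The most abundant transcript in both groups was Mcpt1, the mucosal mast cell chymase, with 7.21% and 7.46% of all counts in the IEMC libraries and 3.04% and 2.67% in the LPMC libraries. In TPM, Mcpt1, Mcpt2 and Actb ranked highest in IEMC, and Mcpt1, Mcpt4 and Cpa3 in LPMC. All 3 tested mucosal mast cell proteases were higher in IEMC, also when adjusted over the list alone (camera up, adjusted p = 6.81e-14, and adjusted p = 0.464 with an estimated correlation). Mcpt1 (gene ID 17224) was at 71534 ± 2962 CPM in IEMC and 29293 ± 2094 CPM in LPMC (log2 fold change 1.29, SE 0.10, adjusted p = 0.000541). Mcpt2 (gene ID 17225) was 3.72-fold higher in IEMC at 23071 ± 232 against 6199 ± 624 CPM. Mcpt9 was 57.5-fold higher, at 1640.4 ± 125 against 28.5 ± 4.85 CPM. All 8 tested genes of connective tissue mast cells were lower in IEMC, with the same number adjusted over the list alone (camera down, adjusted p = 6.81e-21, and adjusted p = 0.464 with an estimated correlation). Tpsb2 (gene ID 17229), a tryptase, was at 40.9 ± 26.7 CPM in IEMC and 6513 ± 1730 CPM in LPMC (log2 fold change -7.31, SE 0.56, adjusted p = 0.000496), and its log2 fold change was -8.21 without IEMC replicate 2. Cma1 (gene ID 17228) was 29.2-fold lower, Tpsg1 44.2-fold lower and Mcpt4 (gene ID 17227) 3.45-fold lower, with Mcpt4 still at 2653 ± 59.1 CPM in IEMC. Mrgprb2, the receptor for basic secretagogues, had 0 counts in both IEMC libraries and 95.7 and 53.1 CPM in the LPMC libraries, which makes it at least 1250-fold lower in IEMC. These proteases belong to families of close copies, so reads may have been divided between copies and the separate levels of Mcpt1, Mcpt2, Mcpt4, Mcpt9, Cma1, Cma2 and Tpsb2 are uncertain.

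Genes shared by all mast cells were also unevenly distributed. Of the 22 tested pan mast cell genes, 13 were lower in IEMC, 4 were higher and 5 did not pass, against 14 lower and 5 higher adjusted over the list alone (camera down, adjusted p = 4.27e-06, and adjusted p = 0.464 with an estimated correlation). These differences and those of the proteases stand beside a macrophage list (camera down, adjusted p = 5.94e-07, and adjusted p = 0.484 with an estimated correlation) and an immediate early list (camera down, adjusted p = 3.15e-12, and adjusted p = 0.399 with an estimated correlation) that were lower in IEMC and an epithelial list that was higher (camera up, adjusted p = 1.89e-08, and adjusted p = 0.556 with an estimated correlation). The receptor Kit was at 1889.8 ± 39 CPM in IEMC and 4903 ± 1384 CPM in LPMC (log2 fold change -1.38, SE 0.19, adjusted p = 0.00439). The carboxypeptidase Cpa3 was 1.65-fold lower in IEMC at 7886 ± 146 against 13019 ± 1138 CPM. The alarmin receptor Il1rl1 was 2.21-fold lower, the transcription factor Gata2 3.6-fold lower and Cd200r3 8.98-fold lower. The IgE receptor chain Fcer1a was 1.58-fold lower. Its call was lost without IEMC replicate 2, though its log2 fold change stayed close (-0.66, against -0.62 without that library). Cd63, a granule membrane protein, went the other way at 5160.1 ± 142 CPM in IEMC and 1381 ± 57.8 CPM in LPMC (log2 fold change 1.90, SE 0.10, adjusted p = 0.000139). The leukocyte marker Ptprc was at 324 ± 9.29 CPM in IEMC and 373 ± 82 CPM in LPMC and did not pass (adjusted p = 0.408), though without LPMC replicate 2 it passed as lower in IEMC (adjusted p = 0.0281) and without LPMC replicate 4 its log2 fold change was 0.07.

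**Figure D2:**
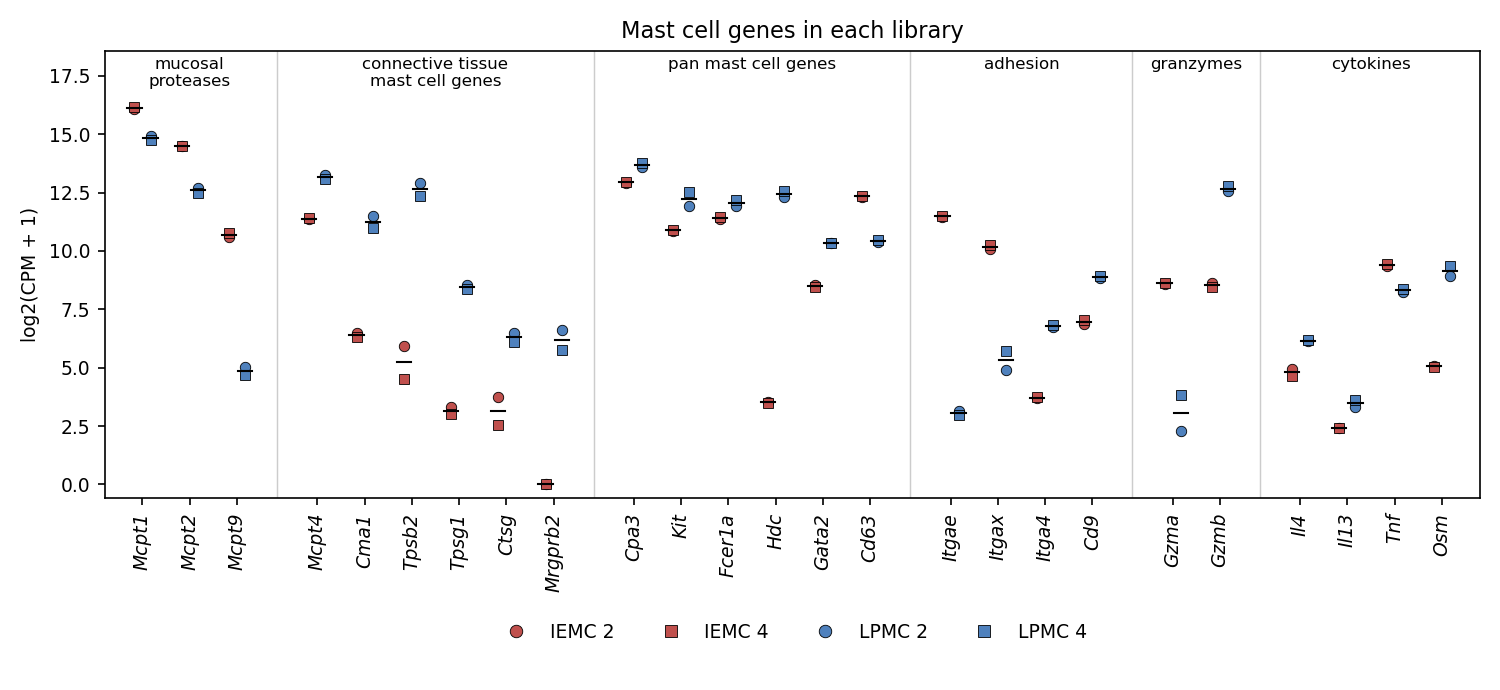
Level of selected mast cell genes in each library, as log2(CPM + 1) on the y axis, with IEMC in red, LPMC in blue, circles for replicate 2, squares for replicate 4 and a black bar at the mean of the log2 values. Mcpt9, Itgae and Itgax are higher in both IEMC libraries, and Hdc, Tpsb2 and Gzmb are higher in both LPMC libraries.

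Adhesion genes went both ways. Of 21 tested integrins and adhesion molecules, 4 were higher and 5 lower in IEMC, with the same numbers adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.115). Itgax was 28.7-fold higher in IEMC at 1155 ± 104 against 40.2 ± 15.9 CPM, and Pecam1 was 2.75-fold higher. Itga4, an integrin chain used for entry from blood, was at 12.1 ± 0.264 CPM in IEMC and 109 ± 4.53 CPM in LPMC (log2 fold change -3.17, SE 0.14, adjusted p = 8.64e-05). The tetraspanin Cd9 was 3.85-fold lower in IEMC. Itgb7, the partner chain of both Itgae and Itga4, chosen after its values were seen, was at 1449.5 ± 139.5 CPM in IEMC and 1252 ± 141 CPM in LPMC and did not pass. The sphingosine phosphate receptor S1pr1 was 9.4-fold higher in IEMC at 60.5 ± 0.539 against 6.44 ± 0.881 CPM. TGF-beta pathway genes went both ways, with 6 of 18 higher and 5 lower (7 and 5 adjusted over the list alone; camera adjusted p = 0.921). Ldlrad4, an inhibitor of TGF-beta signalling, was at 337 ± 17.3 CPM in IEMC and 21.9 ± 4.74 CPM in LPMC (log2 fold change 3.94, SE 0.18, adjusted p = 9.99e-05). Tgif1 was 4.79-fold and Runx1 2.63-fold lower in IEMC.

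Among tissue residency genes, 6 of 18 were lower and 3 higher in IEMC, against 6 and 4 adjusted over the list alone (camera down, adjusted p = 0.000994, and adjusted p = 0.464 with an estimated correlation). The list call was lost when any 1 library was left out, with adjusted p from 0.135 without IEMC replicate 2 to 0.375 without LPMC replicate 2, at 0.146 without IEMC replicate 4 and 0.314 without LPMC replicate 4, and it was lost with no filter on low counts (0.0689). The granule proteases of the list split. Gzmb was at 368 ± 29.5 CPM in IEMC and 6494 ± 631 CPM in LPMC (log2 fold change -4.14, SE 0.13, adjusted p = 2.96e-05). Gzma, chosen after its values were seen, was at 389.6 ± 3.53 CPM in IEMC and 8.51 ± 6.59 CPM in LPMC (log2 fold change 5.52, SE 0.53, adjusted p = 0.00104). Its log2 fold change was 4.89 without LPMC replicate 2 and 6.68 without LPMC replicate 4. The orphan nuclear receptors Nr4a1 and Nr4a2 were 16.6-fold and 39.9-fold lower in IEMC, and Rgs1 was 3.43-fold higher. Nr4a1 and Nr4a2 are also known to respond to stimulation and tissue handling, and the immediate early list was lower in IEMC as well (camera down, adjusted p = 3.15e-12, and adjusted p = 0.399 with an estimated correlation).

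Of 17 tested cytokines and growth factors, 11 were lower and 1 was higher, against 12 and 2 adjusted over the list alone (camera down, adjusted p = 0.000125, and adjusted p = 0.484 with an estimated correlation). The gp130 cytokines Osm and Lif were 17.5-fold and 7.95-fold lower in IEMC, with Osm at 32.4 ± 0.808 against 567 ± 118 CPM. Il4 was at 26.9 ± 3.55 CPM in IEMC and 70.2 ± 1.39 CPM in LPMC (log2 fold change -1.39, SE 0.16, adjusted p = 0.00206). Il13 was at 4.3 ± 0.0201 CPM in IEMC and 10.1 ± 1.63 CPM in LPMC (log2 fold change -1.23, SE 0.34, adjusted p = 0.0447). The Il13 call was lost without IEMC replicate 2 (adjusted p = 0.205), without IEMC replicate 4 (0.206) and without LPMC replicate 4 (0.0798), and also under upper quartile scaling (0.0559), under library size scaling (0.0537) and with no filter on low counts (0.0612). Il1b and Il1a, chosen after their values were seen, were lower in IEMC, with Il1b at 47.8 CPM in LPMC replicate 2 and 127 CPM in LPMC replicate 4 and Il1a at 6.8 and 18.3 CPM. Several macrophage markers and MHC class II genes, given below, were also higher in LPMC replicate 4, and the immediate early list was lower in IEMC (camera down, adjusted p = 3.15e-12, and adjusted p = 0.399 with an estimated correlation). The log2 fold changes of Il1b and Il1a were -5.85 and -6.44, against -4.95 and -5.53 without LPMC replicate 4. That of Il1b was -5.17 without IEMC replicate 2 and -7.14 without IEMC replicate 4. Tnf was the cytokine higher in IEMC, at 677 ± 30.4 CPM in IEMC and 316 ± 17.8 CPM in LPMC (log2 fold change 1.10, SE 0.10, adjusted p = 0.001). Il5 and Tpsab1, which were also to be named whatever their values, were not analysed here.

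Chemokines and their receptors were lower for 9 of 23 members and higher for 3, against 12 and 3 adjusted over the list alone (camera down, adjusted p = 0.00053, and adjusted p = 0.464 with an estimated correlation). The macrophage list (camera down, adjusted p = 5.94e-07, and adjusted p = 0.484 with an estimated correlation) and the immediate early list (camera down, adjusted p = 3.15e-12, and adjusted p = 0.399 with an estimated correlation) were lower in IEMC too. Ccl2 was 11.5-fold and Ccl3 4.22-fold lower in IEMC, with Ccl2 at 171 CPM in LPMC replicate 2 and 199 CPM in LPMC replicate 4 and Ccl3 at 178 and 179 CPM. Cxcl10 was at 0.18 ± 0.199 CPM in IEMC and 34.6 ± 7.39 CPM in LPMC, with log2 fold changes of -9.59 without IEMC replicate 2 and -6.71 without IEMC replicate 4. Cytokine receptors were lower for 11 of 23 and higher for 4, the same numbers as adjusted over the list alone (camera down, adjusted p = 0.00732, and adjusted p = 0.556 with an estimated correlation). This list call was lost without LPMC replicate 4 (adjusted p = 0.109). Tnfrsf9 was 9.55-fold, Il10ra 2.95-fold and Ifnar1 2.51-fold lower, and Il1rap was 3.29-fold higher. In the interferon response list, 5 of 18 were lower and 4 higher (8 and 4 adjusted over the list alone; camera adjusted p = 0.143). That list passed without LPMC replicate 2 (adjusted p = 0.0262). The ubiquitin-like Isg15 was 20.4-fold, Gbp2 3.4-fold and Gbp3 16-fold lower in IEMC, with Gbp3 at a log2 fold change of -4.83 without IEMC replicate 4, whereas Stat2, which carries the interferon signal, was 3.65-fold higher.

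Lipid mediator and purine receptor genes included several large differences. Of 13 tested eicosanoid synthesis genes, 4 were lower and 1 was higher in IEMC, as also adjusted over the list alone (camera down, adjusted p = 0.0238, and adjusted p = 0.497 with an estimated correlation). The list call was lost without IEMC replicate 2 (adjusted p = 0.064) without LPMC replicate 4 (0.109) and with no filter on low counts (0.0535). The inducible cyclooxygenase Ptgs2 was at 12.4 ± 1.39 CPM in IEMC and 691 ± 346 CPM in LPMC (log2 fold change -5.81, SE 0.40, adjusted p = 0.000343), with a log2 fold change of -5.15 without LPMC replicate 4. Ptgs2 was at 447 CPM in LPMC replicate 2 and 936 CPM in LPMC replicate 4, a ratio of 2.09 (log2 ratio 1.07). The macrophage markers called lower had a median ratio of 2.61, with quartiles of the log2 ratio at 0.197 and 1.81. Other genes called lower had quartiles of -0.126 and 0.281 and ranged from -2.17 to 4.31. A macrophage source of Ptgs2 was not tested. The macrophage list (camera down, adjusted p = 5.94e-07, and adjusted p = 0.484 with an estimated correlation) and the immediate early list (camera down, adjusted p = 3.15e-12, and adjusted p = 0.399 with an estimated correlation) were lower in IEMC along with this list. Ptgs1 was 3.14-fold and the leukotriene enzyme Alox5 1.78-fold lower, whereas its partner Alox5ap was 1.72-fold higher. Purinergic receptors and ectoenzymes were lower for 5 of 15 and higher for 2, against 6 and 3 adjusted over the list alone (camera down, adjusted p = 0.0231, and adjusted p = 0.556 with an estimated correlation). This list call was lost without IEMC replicate 2, IEMC replicate 4, LPMC replicate 2 or LPMC replicate 4 (adjusted p = 0.261, 0.402, 0.0886 and 0.568) and with no filter on low counts (0.169). The adenosine receptors Adora2a, Adora2b and Adora3 were 18.5-fold, 16.3-fold and 3.77-fold lower in IEMC, and the nucleotide receptor P2ry2 was 4.69-fold higher. P2rx7, the ATP-gated channel, was at 884 ± 58.7 CPM in IEMC and 720.4 ± 104 CPM in LPMC and did not pass (adjusted p = 0.154), but passed as higher in IEMC without LPMC replicate 4 (adjusted p = 0.0204).

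Of 20 tested members of the degranulation machinery, 2 were higher and 1 was lower in IEMC and 17 did not pass, the same as adjusted over the list alone (camera adjusted p = 0.973). Not passing does not show that their levels were equal. Rab27b, a GTPase of granule transport, was at 89.5 ± 5.88 CPM in IEMC and 467 ± 24.6 CPM in LPMC (log2 fold change -2.38, SE 0.11, adjusted p = 0.000109). The SNARE protein Vamp8 was 2.06-fold higher in IEMC. Stx3 was 1.47-fold higher, a call lost without IEMC replicate 2 (adjusted p = 0.103) and without IEMC replicate 4 (0.12). Rab3a was at 5.86 ± 0.387 CPM in IEMC and 2.47 ± 0.187 CPM in LPMC and did not pass (adjusted p = 0.0931), though it passed with limma on log2(FPKM + 1) (adjusted p = 0.0116). Glycosaminoglycan synthesis genes build the heparin and chondroitin sulfate of granules. They were lower for 6 of 23 and higher for 5, against 9 and 5 adjusted over the list alone (camera adjusted p = 0.28). The rotation test fry called this list down (adjusted p = 0.0381). Hs3st1, a sulfotransferase that acts on heparan chains, was at 215 ± 26.8 CPM in IEMC and 2133 ± 227 CPM in LPMC (log2 fold change -3.31, SE 0.14, adjusted p = 8.52e-05). Hs6st1 was 2.61-fold and Papss2 1.66-fold lower, and Chst12 was 2.2-fold higher.

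Of 26 tested cell cycle genes, 19 were lower, 0 were higher and 7 did not pass, with 22 lower adjusted over the list alone (camera down, adjusted p = 2.02e-07, and adjusted p = 0.497 with an estimated correlation). The macrophage list (camera down, adjusted p = 5.94e-07, and adjusted p = 0.484 with an estimated correlation) and the immediate early list (camera down, adjusted p = 3.15e-12, and adjusted p = 0.399 with an estimated correlation) were lower in IEMC as well, and the epithelial list was higher (camera up, adjusted p = 1.89e-08, and adjusted p = 0.556 with an estimated correlation). Mki67 was at 133 ± 3.58 CPM in IEMC and 289.8 ± 23.5 CPM in LPMC (log2 fold change -1.12, SE 0.11, adjusted p = 0.00129). The mitotic genes Top2a, Kif11 and Tpx2 were 2.44-fold, 3.05-fold and 2.32-fold lower. Cholesterol synthesis genes were higher in IEMC for 7 of 20 members and lower for 0, and 11 were higher adjusted over the list alone (camera up, adjusted p = 0.014, and adjusted p = 0.556 with an estimated correlation). Sc5d was 1.98-fold and Mvd 2.71-fold higher. Msmo1 (1.96-fold) and Idi1 (1.84-fold) were higher as well, calls lost without IEMC replicate 2 (adjusted p = 0.0634 and 0.0551) and, for Idi1, without IEMC replicate 4 (0.0545). Glycolysis genes divided into 3 higher, 5 lower and 10 not past the threshold (4 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.319). The hexokinase Hk2 was 6.47-fold lower in IEMC at 26.8 ± 0.704 against 173 ± 29.6 CPM, Pfkp was 2.69-fold and Hk1 1.98-fold lower, and Eno1 was 1.76-fold higher.

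Immediate early and dissociation stress genes, which respond to stimulation and also to tissue handling, were lower in IEMC for 15 of 26 members and higher for 1, against 19 and 3 adjusted over the list alone (camera down, adjusted p = 3.15e-12, and adjusted p = 0.399 with an estimated correlation). Fosb was at 244 ± 13.8 CPM in IEMC and 2519.5 ± 2.54 CPM in LPMC (log2 fold change -3.37, SE 0.11, adjusted p = 2.96e-05). Atf3 was 75.4-fold and Junb 5.58-fold lower in IEMC. Jun went the other way, 1.57-fold higher in IEMC, a call lost without IEMC replicate 2 (adjusted p = 0.107). Of the 7 heat shock genes on this list, 2 were called lower in IEMC and 5 did not pass, and 6 had a log2 fold change below 0. No mitochondrially encoded gene was analysed here.

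Gasdermin and inflammasome genes gave 3 higher and 2 lower of 13 (4 and 2 adjusted over the list alone; camera adjusted p = 0.973). Nlrp3, the sensor of an inflammasome, had 0 counts in both IEMC libraries and 22.7 ± 2.88 CPM in LPMC, at least 380-fold lower in IEMC. Gsdmc2 was at 3.57 ± 0.678 CPM in IEMC, with 4.05 CPM in IEMC replicate 2 and 3.09 CPM in IEMC replicate 4. Gsdmc4 was at 3.16 CPM in IEMC replicate 2 and 9.66 CPM in IEMC replicate 4. Both had 0 counts in LPMC, which makes them at least 54.4-fold and 98.1-fold higher in IEMC. The epithelial list was higher in IEMC too (camera up, adjusted p = 1.89e-08, and adjusted p = 0.556 with an estimated correlation). An epithelial source of Gsdmc2 and Gsdmc4 was not tested. These 2 genes are near-identical copies and their separate levels are uncertain, and the Gsdmc2 call was lost without IEMC replicate 2 (adjusted p = 0.056). Gsdme was 1.65-fold lower, a call lost without IEMC replicate 2 (adjusted p = 0.0671) and without IEMC replicate 4 (0.0888).

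**Figure D3:**
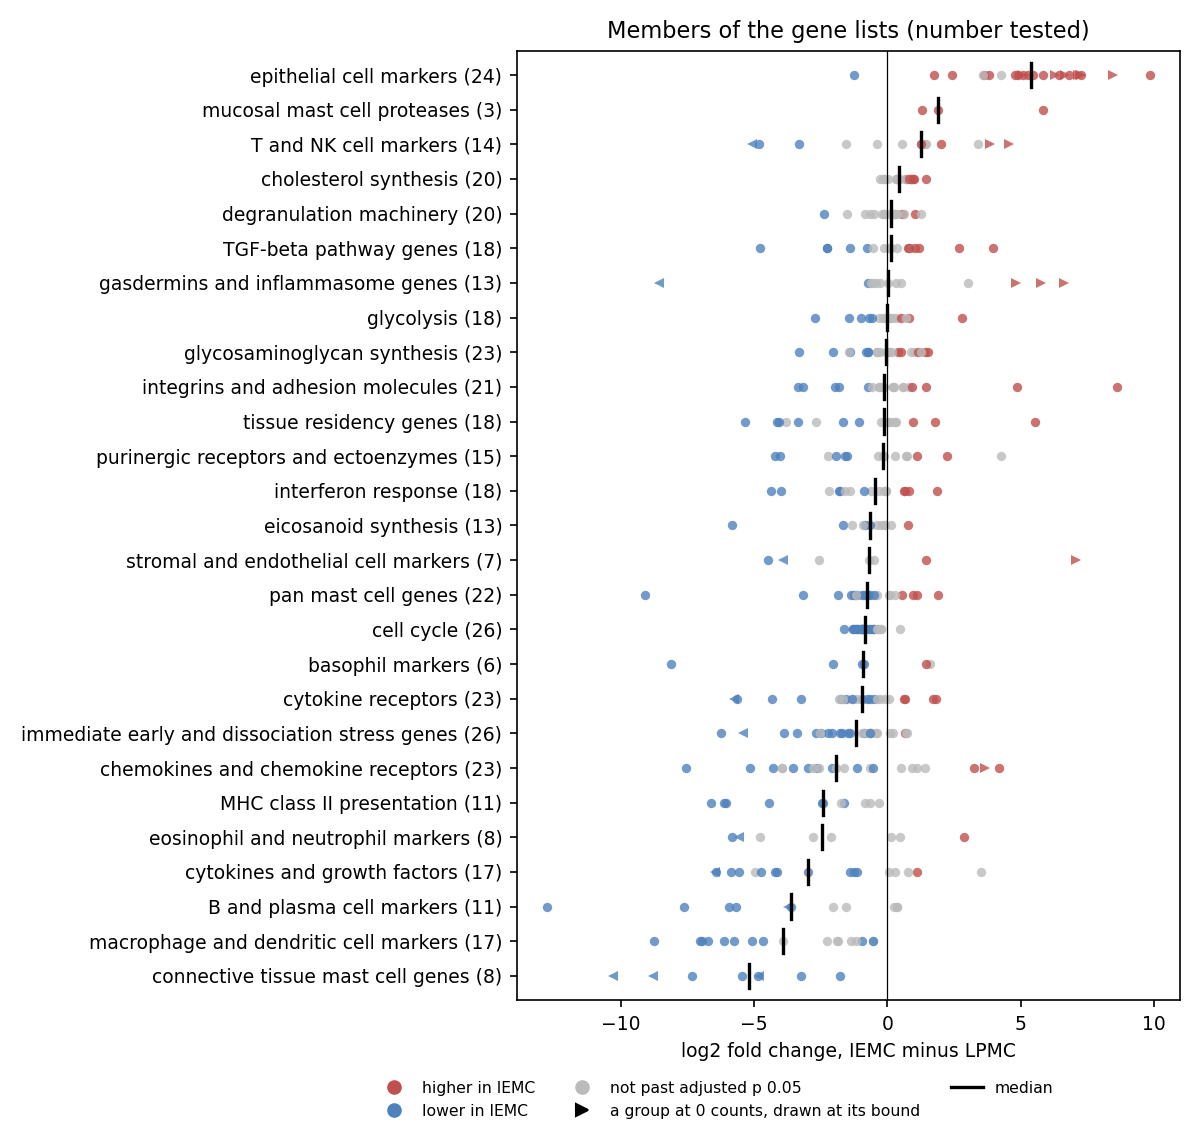
Log2 fold change (x axis, IEMC minus LPMC) of each tested member of the 27 tested gene lists (y axis, number of tested members in parentheses), coloured by call, with triangles for members at 0 counts in a group, placed at their lower bound, and a black bar at the list median. All 3 mucosal mast cell proteases lie to the right of 0 and all 8 connective tissue mast cell genes to the left.

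For some lists that were not called, the median log2 fold change, the mean and the direction of camera differed in sign. Integrins and adhesion molecules had a median of -0.12, a mean of 0.28 and the direction up, and stromal markers a median of -0.70 and a mean of -0.50 with the direction up. T and NK cell markers had a median of 1.26 and a mean of 0.60 with the direction down, and degranulation machinery a median of 0.13 and a mean of -0.05 with the direction down. For TGF-beta pathway genes the median was 0.12, the mean was -0.00361 and the direction was up. For glycolysis the median was 0.00213, the mean was -0.0795 and the direction was down. Gasdermin and inflammasome genes had a median of 0.0126 and a mean of 1.34, with the direction up by camera and down by the rotation test fry.

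Markers of other cell types differed as well, and differed between replicates. Of 24 tested epithelial cell markers, 21 were higher and 1 lower in IEMC, against 22 and 1 adjusted over the list alone (camera up, adjusted p = 1.89e-08, and adjusted p = 0.556 with an estimated correlation). Epcam was at 23.4 ± 7.74 CPM in IEMC and 1.67 ± 1.69 CPM in LPMC (log2 fold change 3.81, SE 0.76, adjusted p = 0.0154). Its log2 fold change was 3.03 without LPMC replicate 2 and 5.63 without LPMC replicate 4. Krt19 was at 16.7 CPM in IEMC replicate 2 and 52.2 CPM in IEMC replicate 4, and Reg3g at 20.1 and 47.7 CPM, while both stayed under 1 CPM in LPMC. Over the 21 markers called higher, the median ratio of IEMC replicate 4 to IEMC replicate 2 was 2.55. Cdh1 (E-cadherin, gene ID 12550) differed from that pattern, at 276 CPM in IEMC replicate 2 and 275 CPM in IEMC replicate 4 against 10.1 ± 8.71 CPM in LPMC (log2 fold change 4.77, SE 0.59, adjusted p = 0.00264). Its log2 fold change was 4.08 without LPMC replicate 2 and 6.14 without LPMC replicate 4. Anpep was the marker lower in IEMC, 2.36-fold.

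Several markers of myeloid and plasma cells were higher in LPMC. Of 17 tested macrophage and dendritic cell markers, 10 were lower and 0 higher in IEMC, as also adjusted over the list alone (camera down, adjusted p = 5.94e-07, and adjusted p = 0.484 with an estimated correlation). Lyz2 was at 41.2 CPM in LPMC replicate 2 and 162 CPM in LPMC replicate 4, Csf1r at 30.4 and 72.5 CPM and C1qa at 12 and 44.3 CPM, while all 3 stayed under 1 CPM in IEMC. Apoe was closer between the LPMC libraries, at 219 and 245 CPM against 9.26 ± 0.119 CPM in IEMC. MHC class II presentation genes were lower in IEMC for 7 of 11 members and higher for 0, with 8 lower adjusted over the list alone (camera down, adjusted p = 0.00138, and adjusted p = 0.556 with an estimated correlation). Like Lyz2, Csf1r and C1qa, they were higher in LPMC replicate 4. Cd74 was at 229.9 CPM in replicate 2 and 797 CPM in replicate 4. H2-Ab1 was at 108 and 348 CPM, H2-Eb1 at 42.5 and 179.9 CPM and H2-Aa at 37.2 and 177 CPM. The log2 fold change of Cd74 was -6.12, against -6.76 without LPMC replicate 2 and -4.94 without LPMC replicate 4, and all 4 stayed past the threshold without any single library. B and plasma cell markers were lower for 6 of 11 and higher for 0, as also adjusted over the list alone. That list was not called (camera adjusted p = 0.073). It passed without LPMC replicate 2 (adjusted p = 0.000977), under upper quartile scaling (0.0446), under library size scaling (0.0475) and with no filter on low counts (0.0199). The antibody joining chain Jchain was at 79.9 and 543 CPM in the LPMC libraries against 2 counts in all of IEMC, a ratio of 7770 (interval 2150 to 64200). Its log2 fold change was -12.76, against -13.56 without LPMC replicate 2 and -10.77 without LPMC replicate 4, a spread that the counting interval leaves out.

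T and NK cell markers gave 4 higher and 3 lower of 14 (5 and 3 adjusted over the list alone; camera adjusted p = 0.393). Nkg7, a granule protein of cytotoxic cells, was 9.9-fold lower in IEMC at 6.33 ± 0.284 against 62.7 ± 11 CPM. Basophil markers were lower for 4 of 6 and higher for 1, as also adjusted over the list alone (camera down, adjusted p = 0.00179, and adjusted p = 0.464 with an estimated correlation). This call was lost without IEMC replicate 2, IEMC replicate 4, LPMC replicate 2 or LPMC replicate 4 (adjusted p = 0.118, 0.0782, 0.159 and 0.154) and with no filter on low counts (0.0509). Prss34 was at 0.716 ± 0.219 CPM in IEMC and 200.2 ± 29.9 CPM in LPMC (log2 fold change -8.12, SE 0.25, adjusted p = 2.96e-05). Mcpt8 was 4.15-fold lower and the receptor Fcgr3 2.71-fold higher. Eosinophil and neutrophil markers gave 1 higher and 2 lower of 8 (1 and 5 adjusted over the list alone; camera adjusted p = 0.393). The list passed as lower without LPMC replicate 2 (adjusted p = 0.0278). Siglecf was 7.31-fold higher in IEMC at 98.2 ± 8.32 against 13.4 ± 2.44 CPM. Mmp9 was at 0.419 ± 0.201 CPM in IEMC and 23.8 ± 2.04 CPM in LPMC, with a log2 fold change of -6.40 without IEMC replicate 2. Stromal and endothelial markers gave 2 higher and 2 lower of 7, as also adjusted over the list alone (camera adjusted p = 0.494). Myh11 was at 8.77 ± 2.04 CPM in IEMC and 0 counts in LPMC, which makes it at least 134-fold higher. The calls on Cd4, Klrb1c, Mzb1, Col3a1 and Dcn, each under 5 CPM in both groups, were lost without IEMC replicate 2 (adjusted p = 0.0972, 0.214, 0.0648, 0.126 and 0.219). Apart from Col3a1 they were lost without IEMC replicate 4 as well (Cd4 0.0926, Klrb1c 0.0822, Mzb1 0.0804, Dcn 0.229), and apart from Klrb1c also without LPMC replicate 4 (Cd4 0.089, Mzb1 0.183, Col3a1 0.0978, Dcn 0.0934). The call on Dcn was lost without LPMC replicate 2 too, and with no filter on low counts (adjusted p = 0.0738).

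**Figure D4:**
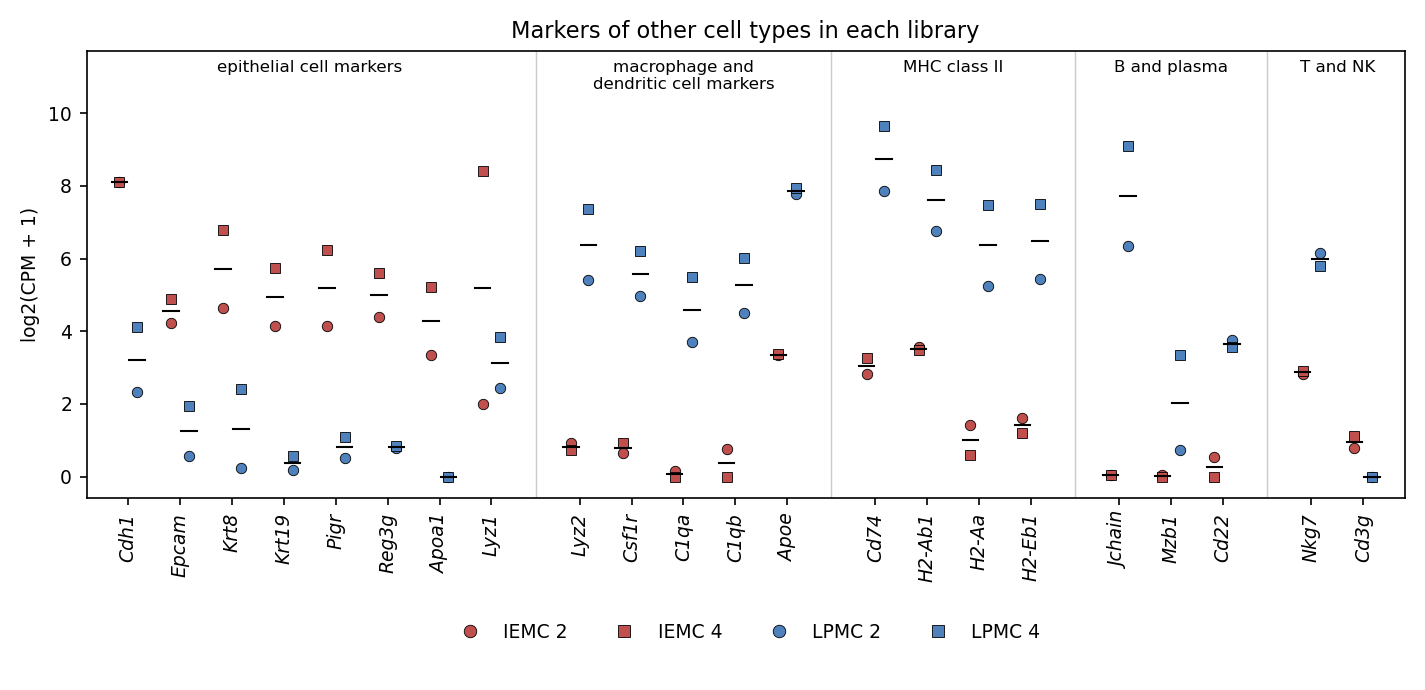
Level of markers of other cell types and of MHC class II genes in each library, as log2(CPM + 1) on the y axis, with IEMC in red, LPMC in blue, circles for replicate 2, squares for replicate 4 and a black bar at the mean of the log2 values. Epithelial markers other than Cdh1 are higher in IEMC replicate 4 than in IEMC replicate 2, and Lyz2, Jchain and Cd74 are higher in LPMC replicate 4 than in LPMC replicate 2.

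The largest fitted differences at 10 CPM or more were mostly in genes with 0 counts in the other group, for which the fold is a lower bound against 3 counts over the group. Such bounds, and the 95% interval given for Jchain, cover counting error only. Among the 12 higher in IEMC, Speg, a muscle-type kinase, was at 72.6 ± 5.33 CPM and at least 1110-fold higher. The neurotensin receptor Ntsr1 (27.6 ± 5.31 CPM), the proteoglycan Cspg4 (26.4 ± 2.33 CPM), Adgra1 (23.4 ± 0.591 CPM) and Adam23 (16 ± 1.55 CPM) were at least 421-fold, 402-fold, 357-fold and 244-fold higher. Genes known from epithelial cells made up the rest and differed between the IEMC libraries. In replicates 2 and 4, Olfm4 was at 18.7 and 74.6 CPM, Cps1 at 15.5 and 67.2 CPM, Lgals2 at 10.8 and 42.5 CPM, Apoa1 at 9.21 and 36.4 CPM, and Chgb at 8.57 and 32.3 CPM. Reg4 went the other way at 30 and 4.83 CPM. Defa31, a member of a family of close copies, was at 0.841 and 46 CPM, and its call was lost without IEMC replicate 4 (adjusted p = 0.23), LPMC replicate 2 (0.0931) or LPMC replicate 4 (0.0853), with RLE scaling (0.0528), with no filter on low counts (0.0708) and with robust moderation (0.133).

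Among the 12 lower in IEMC, Pmp22, a membrane protein known from myelin, was detected in both groups at 0.159 ± 0.055 CPM in IEMC and 419 ± 109 CPM in LPMC (log2 fold change -11.31, SE 0.35, adjusted p = 2.96e-05). Mrgprb1 was at 36 CPM in LPMC replicate 2 and 16.1 CPM in LPMC replicate 4, at least 438-fold lower in IEMC. The amylase copies Amy2a5 and Amy2a1, which cannot be separated with certainty, were at 39.1 and 21.1 CPM in LPMC replicate 2 and at 13 and 8.94 CPM in LPMC replicate 4. The lectin Clec10a (15.9 ± 4.64 CPM) and the chemokine Ccl24 (7.36 CPM in LPMC replicate 2, 17.6 CPM in LPMC replicate 4) were at least 265-fold and 208-fold lower. Myeloid genes in this set differed between the LPMC libraries, with Il1rn at 5.02 CPM in replicate 2 and 38.4 CPM in replicate 4, Clec7a at 2.73 and 35.9 CPM and Acod1 at 1.3 and 35.2 CPM. The Acod1 call was lost without IEMC replicate 2 (adjusted p = 0.0585) without LPMC replicate 4 (0.0662) and with no filter on low counts (0.0503). Nlrp3, Mrgprb2 and Jchain, described above, completed the set.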

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

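The count of genes whose higher group had its libraries within 1.5-fold of each other was chosen after the results were seen, and the other settings were fixed before the data were examined. None of the 3246 calls had the opposite call in any setting run on all genes. Scaling, filters, robust moderation, DESeq2, limma on FPKM or TPM and leaving out genes of other cell types gave 2674 to 3798 calls. More genes were higher than lower under upper quartile scaling (1842 and 1457), library size scaling (1773 and 1490), limma on log2(FPKM + 1) (1855 and 1472) and log2(FPKM + 0.1) (1789 and 1440) and without LPMC replicate 4 (1843 and 1577), and fewer in the other settings. Of the 3246 calls, 2738 (1314 higher, 1424 lower) had libraries within 1.5-fold. A test against a fold of 1.5 gave 1684 calls, 776 higher and 908 lower, because it asks for a larger difference. Leaving out 1 library gave 1556 to 3420 calls, 676 to 1843 higher and 880 to 1735 lower, with the lowest count without IEMC replicate 4. The group left with 1 library is then assumed to vary like the other group. A call can then be lost with little change of the fold, as for Fcer1a without IEMC replicate 2. Of 181 named genes tested, 170 passed. Of these, 144 lost the call in none of the 18 alternatives that tested them, and none of the 170 turned direction. Of all 3246 calls, 51.9% were kept in the test against a fold of 1.5, but most named genes were picked for their values in the main fit. The named genes are therefore not a sample of all calls. Among genes that did not pass, leaving out 1 library gave log2 fold changes of -1.55 to 5.32 for Lyz1, -0.41 to 0.066 for Ptprc and -0.010 to 0.28 for Dnajb1, and the cause was not tested. The replicate numbers are not known to pair the libraries, and the deviations of equal numbers correlated weakly over genes (r = 0.0982, rho = 0.0669). With the number as a replicate block 3502 genes and 17 lists were called, with the B and plasma cell list added (adjusted p = 0.000453). The calls on Il13 (adjusted p = 0.0508) and Dcn (0.0532) were lost with that block.

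Of 27 lists, 16 were called with the preset correlation, 0 with an estimated correlation, 9 with fry and 11 to 16 with 1 library left out. Fry kept 8 of the 16 and added glycosaminoglycan synthesis (fry adjusted p = 0.0381). It lost epithelial markers (0.104), macrophage and dendritic cell markers (0.0643), MHC class II genes (0.123) and cholesterol synthesis (0.115). Cytokines (0.0593), cytokine receptors (0.107), eicosanoid synthesis (0.0643) and purinergic receptors (0.104) were lost with fry as well. The simulated list of raised genes was missed both by fry (adjusted p = 0.115) and by camera with an estimated correlation (0.243). A loss with either therefore does not show that a list was unchanged. Only lists that were not called turned direction, and the cause was not tested. Degranulation machinery turned up under upper quartile scaling (adjusted p = 0.974), library size scaling (0.991), no filter (0.685), the stricter filter (0.896), the block (0.997) and without 1 library (0.547 to 0.869). Gasdermin and inflammasome genes turned down under upper quartile scaling (0.974) and fry (0.818) and without LPMC replicate 2 (0.658 to 0.858 over the libraries left out). T and NK cell markers turned up with no filter (0.568) and without 1 library (0.302 to 0.858), stromal markers turned down with no filter (0.48) and without 1 library (0.098 to 0.47), and integrins turned down without IEMC replicate 4 or LPMC replicate 2 (0.568 to 0.834 over the libraries left out). At 2 libraries per group, the simulation recovered 47 of 100 genes changed by a fold of 2, so smaller differences can be missed at this depth and number. It changed only 200 genes, where 3246 were called in the data. Its adjusted threshold was therefore stricter, and the share recovered need not hold for the data.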

Other observations

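The genes and tests in this part were chosen after the results were seen, except for the camera test of the TGF-beta list. Among genes that no list held, IEMC carried more RNA for several surface and secreted proteins. The serine protease Htra1 was at 311 ± 75.8 CPM in IEMC and 0.393 ± 0.00468 CPM in LPMC (log2 fold change 9.61, SE 0.30, adjusted p = 2.96e-05). The peptidase Dpp4 was 70.7-fold higher in IEMC, at a log2 fold change of 6.14, against 5.51 without LPMC replicate 2 and 7.33 without LPMC replicate 4. The adhesion receptor Adgrg1 was 13.7-fold, the transferrin gene Trf 17.8-fold and the surface protein Cd24a 33-fold higher. LPMC carried more RNA for the receptor partner Ramp3, at 0.518 ± 0.173 CPM in IEMC and 175 ± 13.6 CPM in LPMC (log2 fold change -8.39, SE 0.23, adjusted p = 2.96e-05), and for Calca, the gene of the neuropeptide CGRP, at 0.218 ± 0.139 CPM in IEMC and 70.5 ± 3.56 CPM in LPMC (log2 fold change -8.30, SE 0.34, adjusted p = 6.78e-05, and log2 fold change -9.11 without IEMC replicate 4). The transporter Slco2b1 was 135-fold, the cytokine signalling inhibitor Socs2 67.6-fold and the retinoic acid degrading enzyme Cyp26a1 24.7-fold lower in IEMC.

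Among genes known to be induced by stimulation, which were picked one by one, Sik1 was 116-fold, Nr4a3 20.5-fold, Nfkbiz 12.9-fold and Crem 5.8-fold lower in IEMC. Of genes known to respond to low oxygen, also picked one by one, Ndrg1 was 92-fold and Hilpda 15.9-fold lower in IEMC. P4ha2 (log2 fold change -4.39, adjusted p = 0.000712), Vegfa (-4.20, adjusted p = 0.0129) and Hk2, given above, were lower too. Car9 was 19-fold higher in IEMC at 217 ± 13.2 against 11.4 ± 6.13 CPM, and Eno1, given above, was 1.76-fold higher. The log2 fold change of Car9 was 4.25, and 4.94 without LPMC replicate 2. In the order of the protease genes on chromosome 14 in the GRCm38.p6 gene table, the 4 called higher in IEMC (Cma2, Mcpt1, Mcpt2 and Mcpt9) followed each other, between Cma1 and Mcpt4, which were lower.

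Epithelial markers higher in IEMC moved together between the IEMC libraries. Over 21 of them the median log2 ratio of IEMC replicate 4 to IEMC replicate 2 was 1.35 (quartiles 1.18 and 1.99), against 0.063 (-0.0906 and 0.203) for the other genes called higher, so that epithelial cells or their RNA in the sort are a candidate source. Cdh1 argued against them as its own main source, with a log2 ratio of -0.00595 where the other 20 ranged from 0.673 to 2.6, and Itgae was likewise even, at 0.0431. Epithelial genes did not all move alike, since Reg4, known from secretory epithelial cells and outside the list, was at 30 CPM in IEMC replicate 2 and 4.83 CPM in IEMC replicate 4, but Epcam (17.9 and 28.9 CPM) and Krt8 (23.8 and 109 CPM), known from all epithelial cells, were higher in replicate 4. Expression of Cdh1 by IEMC themselves stays open and was not tested. The gate of the sort, which would be meant to remove epithelial cells, is not given in the sources used here.

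Most macrophage markers and the MHC class II genes were higher in LPMC replicate 4 than in LPMC replicate 2, with median log2 ratios of 1.39 over 10 markers (quartiles 0.197 and 1.81) and 1.68 over 7 class II genes (1.19 and 1.93), against 0.0677 (-0.126 and 0.281) for the other genes called lower. Macrophages or B cells, or their RNA, are a candidate source, but Apoe (0.159), C1qc, Mertk and Cx3cr1 were closer to even and the lowest of the 10 was at -0.197, which leaves a part made by mast cells open. For the 15 genes of the immediate early list called lower the median was 0.235, between the lower quartile (0.122) and the median (1.39) of 16 macrophage and plasma cell markers, so whether macrophage RNA raised them in LPMC cannot be told. A narrower comparison set of 7 macrophage markers nearly absent from IEMC (quartiles 1.39 and 1.91) would have put them below it, but it was picked only after the wider set had left the question open and is not used to decide it. Harsher handling of the lamina propria cannot be told apart from the compartment either, since the groups came from separate tissue layers. Of 7 heat shock members, 2 were called lower in IEMC and 6 had a log2 fold change below 0.

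Connective tissue mast cell genes were lower in LPMC replicate 4 than in LPMC replicate 2, with a median log2 ratio of -0.539 over 8 genes, against 0.273 over 13 pan mast cell genes called lower. The means differed by -0.809 (p = 2.95e-05, 2-sided exact permutation test over genes). That p compares 2 single libraries over genes that are not independent, in a pattern noticed in the same values, so it restates the difference and bears on no explanation. Whether a subset of the LPMC carries these genes stays open.

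A further hypothesis, that TGF-beta signalling was higher in IEMC, was prompted by its targets Itgae and Ldlrad4 and read from the whole TGF-beta list, which was not called (camera adjusted p = 0.921) and so decides nothing.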
